A study of Rattus norvegicus with 47 samples.

How the data were processed

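Kidney RNA of 47 rats was sequenced 12 months after pellets of W, Co, Al, Pb, DU or Ta were implanted, with 7 libraries for Pb and 8 for each other metal. Per the labels, RNA was taken with TRIzol and Phase Lock Gel, treated with DNase and checked on a Bioanalyzer, and a sequencing company made the libraries. The deposited values are raw counts per gene, and per the submitters' processing notes the authors aligned reads with STAR 2.7.2a to the mRatBN7.2 genome and counted them with featureCounts of Subread 1.6.4. The notes do not state the annotation, the strand setting or the treatment of reads that map to several places, so values of genes with near-identical copies or with a gene on the other strand are uncertain.

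The table used held 22525 genes, and 18641 of their symbols (82.8%) were found in the RefSeq table of rat genes. Left out were 29 lines that name no gene, because the coordinate text of 5 very long genes, among them Syne1, Neb, Ttn and Macf1, runs over several lines; these 5 genes are not used here. Total counts per library were 21604755 to 35775818, and mitochondrially encoded genes took 11.8% to 26.5% of them. CPM are counts divided by the library total scaled by its TMM factor, in the usual unit. Depth sets counting error only, and the tests use the spread between animals.

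Each metal was compared with Ta, and metals with each other, in 1 fit over all 47 libraries with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (15868 tested), scaled by TMM and tested by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The common dispersion was 0.124 and the prior degrees of freedom 4.84. Differences among all 6 metals and among the 5 metals without Ta used the same fit with several coefficients. A total of 43 gene lists fixed before the counts were opened was tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry, whose test asks whether a list's genes move one way on balance. Lists needed 3 tested members, and log CPM used a prior count of 2. List counts were adjusted over all genes, and again adjusted over the list alone.

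Genes were named by a rule: up to 10 higher and 10 lower genes by size of change with a mean of at least 1 CPM, a symbol that is not provisional and at least 6 libraries on the same side of the Ta median, and up to 10 members of the fixed lists with the smallest p. A panel of 12 genes (Havcr1, Lcn2, Spp1, Clu, Timp1, Mt1, Mt2A, Hmox1, Nqo1, Cdkn1a, Umod and Cyp24a1) was read in each comparison, and for tests of several metals up to 10 genes with the smallest p were named. Genes given as examples of a list outside this rule were chosen after their values were seen.

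Grouping, the fit above and the following other settings were chosen before the data were examined: DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper quartile factors, no filter and a strict filter (1 CPM in 7 libraries), replicate numbers as a block, covariates of cell make-up, a circadian covariate, surrogate variables of sva 3.50.0 (3 of them), a fold of at least 1.5, a threshold of 0.1, fits of only the groups compared, and fits without each library. The covariates of cell make-up were the mean log2 CPM of proximal tubule S1 and S2 markers and of collecting duct principal cell markers. They hold no podocyte, endothelial, fibroblast or immune cell list. A covariate of the balance between small and very large proteins, and fits without Ta replicates 4 and 6 or DU replicates 5 and 6, were chosen after seeing the data. This balance differed between Ta and the other metals, so fits with it as a covariate cannot fully separate it from the metal. Over all genes and groups, single replicate numbers did not pair libraries. For 115 pairs with the same number the median correlation of residuals was 0.0116 (-0.353 to 0.360), against -0.000744 for other pairs. That median does not cover a split between lower and higher numbers, which Kdr showed in W, Co and Al. Among 161 pairs of libraries within groups none was a copy, the lowest chi-square per degree of freedom being 15.7.

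The scripts were tested on simulated data with 200 changed genes per comparison. They recovered 93.9% to 98.5% of genes changed 4 times, 74.6% to 85.1% of those changed 2 times and 40.3% to 47.8% of those changed 1.5 times, with 4 to 13 false calls. Genes were simulated independently of each other, so these values need not hold for the real libraries. Random splits of the real Pb and Ta libraries called up to 7132 genes, with a median of 0. Animal numbers run in blocks that coincide with the metals, so an effect of handling order cannot be separated from that of the metal.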

Results

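RNA was sequenced from the kidneys of rats that had carried implanted metal pellets for 12 months. The series description states that rats were assigned at random to pellets of tungsten (W), cobalt (Co), aluminium (Al), lead (Pb), depleted uranium (DU) or tantalum (Ta), an inert metal that served as the reference. The 47 libraries comprised 8 kidneys per metal, except 7 for Pb, and the labels give each library its own animal number. Total gene counts ranged from 21604755 to 35775818 per library, with a median of 26363810, and 14538 to 18015 genes had at least 1 count. At this depth counting error weighs mainly on genes near 1 CPM, and the tests rest on the spread between animals.

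Compared with Ta, kidneys with Pb pellets differed in 8517 of 15868 tested genes, of which 3891 were higher and 4626 lower. Kidneys with Co differed in 4089 genes (2161 higher and 1928 lower), those with Al in 3996 (2029 and 1967), those with DU in 2424 (1252 and 1172) and those with W in 283 (225 and 58). The median log2 fold change over all genes lay between -0.07 and -0.01 in each comparison. In every metal group the libraries also differed from Ta in the balance between genes of small and of very large proteins, measured as the mean log2 CPM of ribosomal protein genes minus that of 38 genes of very large proteins. This difference was 1.19 ± 0.24 in Ta (SD, n = 8), 1.64 ± 0.25 in W, 2.04 ± 0.40 in Co, 2.14 ± 0.41 in Al, 2.90 ± 0.45 in Pb (n = 7) and 1.96 ± 0.30 in DU. It lay above every Ta library in 6 of 8 W, 8 of 8 Co, 8 of 8 Al, 7 of 7 Pb and 8 of 8 DU libraries. Those gene sets were chosen after the data were seen.

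**Figure D1:**
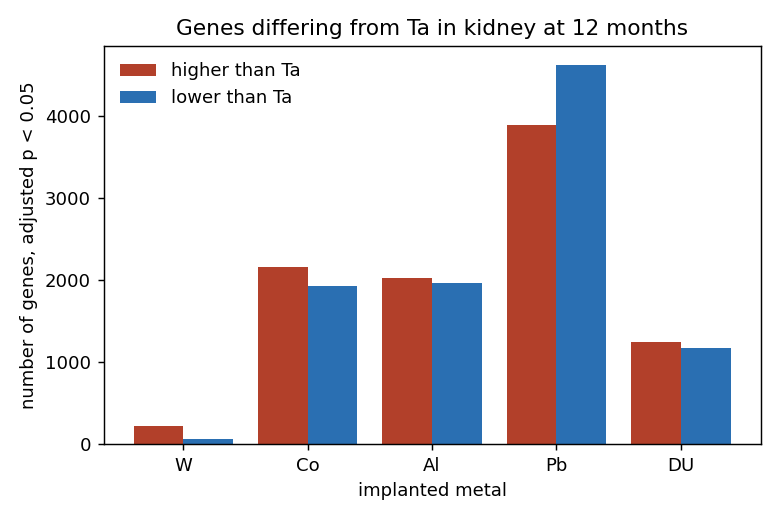
Number of genes higher (left bars) and lower (right bars) than Ta in each metal group at an adjusted p below 0.05, by edgeR's quasi-likelihood test. The y axis is a count of genes and the x axis the implanted metal. Pb had 3891 higher and 4626 lower genes, and W 225 and 58.

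The first comparison asked whether a tungsten pellet changed kidney transcript levels relative to tantalum. In W kidneys 225 genes rose and 58 fell. Ahsa1, which activates the ATPase of the chaperone HSP90, rose from 87.5 ± 5.73 CPM in Ta to 113 ± 15.7 CPM in W (mean ± SD, n = 8 each). Its log2 fold change was 0.37 ± 0.08 (SE, adjusted p = 0.0313), above the Ta median in 7 of 8 libraries. Hspe1, the mitochondrial co-chaperonin, rose by 0.57 ± 0.15 (adjusted p = 0.0365, 8 of 8 libraries). The endoplasmic reticulum chaperone gene Hspa5 (0.35 ± 0.09, adjusted p = 0.0454), Manf (0.47 ± 0.13, adjusted p = 0.0461) and Creld2 (0.50 ± 0.13, adjusted p = 0.0346) also rose. Eln, which encodes elastin, fell by 1.44 on the log2 scale (SE 0.39, adjusted p = 0.0454, 8 of 8 libraries). The smooth muscle genes Tagln (-1.10 ± 0.29, adjusted p = 0.0454) and Acta2 (-0.94 ± 0.26, adjusted p = 0.0495) fell. Among the largest falls were those of Lat2 (-2.24 ± 0.52), Flt3 (-1.52 ± 0.41), Itgb7 (-1.50 ± 0.42), Inpp5d (-1.43 ± 0.37) and Gimap6 (-1.26 ± 0.35), with adjusted p-values from 0.0317 to 0.0480.

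Other genes that rose in W were Ddit4, a stress-induced inhibitor of mTOR signalling (0.60 ± 0.17, adjusted p = 0.0478), Slc17a1, a phosphate transporter of the proximal tubule (0.50 ± 0.12, adjusted p = 0.0320). So did Pomc (0.68 ± 0.18), Sdsl (0.79 ± 0.22), Heatr4 (0.89 ± 0.22), Igip (0.74 ± 0.17), Syce1l (0.65 ± 0.16) and Snrnp25 (0.63 ± 0.16). Genes of small ribosomal or respiratory proteins rose as well, namely Rps29 (0.84 ± 0.20), Rpl38 (0.78 ± 0.19), Ndufa3 (0.81 ± 0.18) and Cox6a1 (0.33 ± 0.09). The gene Chchd2 had the largest rise (1.07 ± 0.28) but a low level, 1.53 ± 0.62 CPM, and near-identical copies elsewhere in the genome make it uncertain. Speg (-1.28 ± 0.27), Hap1 (-1.29 ± 0.36), Aldh1a2 (-1.06 ± 0.28) and Srebf2, a transcription factor of sterol synthesis (-0.37 ± 0.10), fell, the last with an adjusted p of 0.0462.

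By gene list, W had 14 of 43 lists past the threshold of camera, 6 higher and 8 lower. Of 21 nuclear oxidative phosphorylation genes 1 rose over all genes and 17 were higher when adjusted over the list alone (median 0.29, adjusted p = 0.543 with an estimated correlation). Of 14 heat shock genes 2 rose, 4 when adjusted over the list alone (median 0.25, adjusted p = 0.543 with an estimated correlation). Of 18 endoplasmic reticulum stress genes 3 rose, 9 when adjusted over the list alone (median 0.20), at an adjusted p = 0.543 with an estimated correlation. Heme genes (median 0.22, 0 of 13 past the test over all genes and 3 when adjusted over the list alone) and adipocyte markers (median 0.59, 0 of 9 and 1 when adjusted over the list alone) were also called higher, again at an adjusted p = 0.543 with an estimated correlation. So were mitochondrially encoded genes (median 0.21, 0 of 13 and 2 when adjusted over the list alone, adjusted p = 0.676 with an estimated correlation). Lower lists included fibrosis and matrix (median -0.90, 1 of 20 lower and 7 when adjusted over the list alone, adjusted p = 0.615 with an estimated correlation). They also included fibroblasts and pericytes (median -0.85, 1 of 13 and 6 when adjusted over the list alone) and podocytes (median -0.66, 0 of 11 and 7 when adjusted over the list alone), both at an adjusted p = 0.543 with an estimated correlation. Endothelial markers (median -0.60, 0 of 12 and 3 when adjusted over the list alone), T and NK cell markers (median -1.11, 0 of 14 and 2), macrophage markers (median -0.73, 0 of 15 and 0), antigen presentation (median -0.51, 0 of 14 and 6) and distal tubule markers (median -0.63, 0 of 9 and 0) were lower too. Their adjusted p-values with an estimated correlation were 0.615, 0.577, 0.676, 0.657 and 0.657 in that order. The mean log2 CPM of macrophage markers was 4.05 to 4.83 in Ta replicates 4, 5 and 6 and 2.60 to 3.12 in the other Ta libraries, against 1.09 to 4.01 in W. With an estimated correlation camera called 0 lists, with 2 below an unadjusted p of 0.05, and fry called 2.

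The W count rested on single libraries. It rose to 431 without Ta replicate 1, 544 without Ta replicate 5, 435 without Ta replicate 7, 574 without Ta replicate 8, 518 without W replicate 2 and 604 without W replicate 3. It fell to 181 without Ta replicate 4, and the lower genes among it from 58 to 7 without Ta replicate 6. It had 105 higher and 16 lower genes without W replicate 6, and fell to 46 without W replicate 7, 15 without W replicate 8 and 5 without W replicate 5. Each of the 29 named genes that passed the test lost its call without at least 1 library. Leaving out any 1 of 2 libraries ended the call of Ahsa1, any 1 of 5 that of Hspa5 and any 1 of 8 that of Tagln. The highest adjusted p, 0.0872 for Ahsa1, 0.111 for Hspa5 and 0.116 for Tagln, came without W replicate 5. Their log2 fold changes there were 0.35, 0.34 and -1.02, against 0.37, 0.35 and -1.10 with all libraries. W libraries were uneven in genes of vessels and tubules. Kdr ran from 4.63 to 56.3 CPM, below every Ta library in W replicates 5, 6, 7 and 8 and above every Ta library in 2 others. In the same 4 replicates Slc34a3, a phosphate transporter gene, lay below every Ta library, and in the other 4 above every one, over a range of 3.34 to 134.2 CPM. The W means of these genes thus cover values on both sides of the whole Ta range. With the small-protein balance as a covariate, an alternative chosen after seeing the data, edgeR called 0 genes, with 2327 below an unadjusted p of 0.05, where DESeq2 without that covariate called 764 and limma voom 273.

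The comparison of cobalt with tantalum showed a broader change. Cox5b, a subunit of cytochrome c oxidase, rose from 189.8 ± 28.98 to 313 ± 23.4 CPM (mean ± SD, n = 8 each; log2 fold change 0.72 ± 0.11 SE, adjusted p = 1.70e-05), above the Ta median in 8 of 8 libraries. Cd2ap, a scaffold protein of the podocyte slit diaphragm, fell from 75.05 ± 8.49 to 48.3 ± 4.44 CPM (-0.64 ± 0.10, adjusted p = 2.23e-05), below the Ta median in 8 of 8. Ahsa1 (0.52 ± 0.08), Hspe1 (0.90 ± 0.15), Cox6a1 (0.54 ± 0.09), Cox5a (0.47 ± 0.09), the peroxidase gene Prdx1 (0.60 ± 0.11), the sulfotransferase gene Sult1a1 (0.81 ± 0.15) and Bax, an apoptosis effector (0.63 ± 0.11), all rose with adjusted p-values from 2.53e-05 to 0.000202. The mitochondrially encoded ND3 rose from 1073 ± 210.2 to 2187 ± 565 CPM (1.03 ± 0.20, adjusted p = 0.000244).

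Oxidative phosphorylation was the list with the most members past the test in Co. Of its 21 genes 16 rose, 18 when adjusted over the list alone (median 0.40, camera adjusted p = 2.00e-10, adjusted p = 0.698 with an estimated correlation). Of 18 endoplasmic reticulum stress genes 9 rose over all genes and when adjusted over the list alone. First were Creld2 (0.64 ± 0.13) and Manf (0.60 ± 0.13), and the list had an adjusted p = 0.742 with an estimated correlation. In the heat shock list 6 of 14 rose by both counts, Cryab by 0.89 ± 0.26 (adjusted p = 0.698 with an estimated correlation). In the heme list 6 of 13 rose, 8 when adjusted over the list alone, with Blvrb (0.56 ± 0.11), Cpox (0.57 ± 0.14) and Urod (0.39 ± 0.09) first, at an adjusted p = 0.698 with an estimated correlation. Mitochondrially encoded genes rose in 6 of 13, 10 when adjusted over the list alone (adjusted p = 0.742 with an estimated correlation), and took 22.2 ± 2.40% of counts in Co against 19.5 ± 2.52% in Ta.

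Of 20 fibrosis and matrix genes 10 fell in Co, 13 when adjusted over the list alone, including Thbs1 (-1.15 ± 0.27) and Bgn (-1.15 ± 0.30), at an adjusted p = 0.742 with an estimated correlation. Fibroblast and pericyte markers fell in 6 of 13, 10 when adjusted over the list alone, with Rgs5 at -1.48 ± 0.40 and Tagln at -1.24 ± 0.29. Podocyte markers fell in 4 of 11, 9 when adjusted over the list alone, with Plce1 at -0.72 ± 0.18 and Synpo at -1.03 ± 0.32. Both lists had an adjusted p = 0.698 with an estimated correlation. Endothelial markers fell in 4 of 12, 8 when adjusted over the list alone (Cdh5 -0.93 ± 0.33), and interferon genes in 3 of 19, 1 when adjusted over the list alone (Ifit2 -1.49 ± 0.38). Thin limb and medullary markers fell in 3 of 11, 4 when adjusted over the list alone (Slc6a6 -0.78 ± 0.17), and T and NK cell markers in 2 of 14, 1 when adjusted over the list alone (Prf1 -2.16 ± 0.70). For these 4 lists the adjusted p = 0.742 with an estimated correlation. Camera with an estimated correlation called 0 of 43 lists in Co, with 1 below an unadjusted p of 0.05, against 12 with the preset correlation and 14 by fry.

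Genes with the largest falls in Co were mostly of low level. Pde3a, a cyclic nucleotide phosphodiesterase gene, fell by 2.43 on the log2 scale (SE 0.56, adjusted p = 0.00166), from 3.98 ± 1.198 to 0.723 ± 0.952 CPM. The water channel gene Aqp5 fell by 2.09 (SE 0.46, adjusted p = 0.00107). Zfp280b (-1.76 ± 0.47), Plxna4 (-1.83 ± 0.62), Itga8 (-2.07 ± 0.73), Rgs16 (-2.45 ± 0.84), Gxylt2 (-2.13 ± 0.81), Lrrn2 (-1.82 ± 0.67), A2m (-1.78 ± 0.66) and Ddx60 (-1.77 ± 0.63) also fell. Rbp4, the plasma carrier of retinol, rose from 51.5 ± 25.8 to 136.7 ± 73.3 CPM (1.41 ± 0.43, adjusted p = 0.0151, 7 of 8 libraries). Tm4sf20 (1.33 ± 0.33), Ldhc (1.47 ± 0.41), Fbxl22 (1.51 ± 0.43), Kiss1 (1.58 ± 0.56), Rab33a (1.44 ± 0.48) and Fam25a (1.39 ± 0.48) rose. The copies Hist2h2aa2 (2.21 ± 0.41), Hist2h2aa3 (1.36 ± 0.24) and Rpl31l4 (1.43 ± 0.34) are uncertain because their reads are shared with near-identical genes. Of the 30 named genes that passed the test, 20 kept the call without any 1 library. The other 10, each with its highest adjusted p, were A2m (adjusted p = 0.410 without Ta replicate 4), Gxylt2 (0.183) and Rgs16 (0.178), also without Ta replicate 4. They included Lrrn2 (adjusted p = 0.103 without Ta replicate 3), Ddx60 (0.105 without Ta replicate 4), Kiss1 (0.0787 without Co replicate 7), Plxna4 (0.0725 without Ta replicate 8), Itga8 (0.0699 without Ta replicate 6), Rab33a (0.0665 without Co replicate 6) and Fam25a (0.0646 without Co replicate 8). For Rab33a and Fam25a no other library ended the call, while the number was 2 for Plxna4, 4 for Rgs16, 6 for Kiss1, 7 for A2m and for Ddx60, 8 for Itga8, 9 for Gxylt2 and 10 for Lrrn2. The count of 4089 fell to 15 with the small-protein covariate, to 179 with 3 surrogate variables and to 2490 with covariates of cell make-up. The small-protein balance was 2.04 ± 0.40 in Co against 1.19 ± 0.24 in Ta. Co libraries were uneven as well: Kdr ran from 3.07 to 51.2 CPM, below every Ta library in 6 of 8 and above every one in 1. The mean log2 CPM of endothelial markers was 5.01 to 5.57 in Co replicates 1 to 3 and 3.43 to 4.44 in Co replicates 4 to 8. In Ta it was 5.17 to 5.57. The mean log2 CPM of podocyte markers lay below every Ta library in 5 of 8 Co libraries and within the Ta range in the others. The fall of Cd2ap in 8 of 8 thus did not follow that mean.

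In the comparison of aluminium with tantalum, Cox5b rose from 189.8 ± 28.98 to 416 ± 39.1 CPM (mean ± SD, n = 8 each; 1.13 ± 0.11 SE, adjusted p = 4.09e-10), above the Ta median in 8 of 8 libraries. Kdr, the main receptor of vascular endothelial growth factor, fell from 42.1 ± 4.26 to 13.4 ± 13.3 CPM (-1.65 ± 0.53, adjusted p = 0.0198), below every Ta library in 7 of 8. Wt1, a transcription factor of podocytes, fell by 1.43 on the log2 scale (SE 0.45, adjusted p = 0.0172), and Slc4a4, the basolateral bicarbonate transporter of the proximal tubule, fell by 1.67 (SE 0.60, adjusted p = 0.0354). Cyp24a1, the enzyme that breaks down vitamin D, was the gene of the fixed panel that fell in Al, from 115 ± 49.6 to 63.1 ± 16.8 CPM (-0.86 ± 0.27, adjusted p = 0.0172), below the Ta median in 8 of 8 libraries. Without Ta replicate 1 its adjusted p was 0.0671.

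Of 21 oxidative phosphorylation genes 16 rose in Al, 17 when adjusted over the list alone (median 0.39, adjusted p = 0.774 with an estimated correlation), among them Cox6a1 (0.84 ± 0.09), Cyc1 (0.48 ± 0.08) and Cox4i1 (0.53 ± 0.10). Podocyte markers fell in 8 of 11, 9 when adjusted over the list alone (median -0.82), with Synpo at -1.31 ± 0.32 and Cd2ap at -0.54 ± 0.10 (adjusted p = 0.774 with an estimated correlation). Fibroblast and pericyte markers fell in 7 of 13, 11 when adjusted over the list alone (median -0.98), with Rgs5 at -1.43 ± 0.39 and an adjusted p = 0.774 with an estimated correlation. Endothelial markers fell in 8 of 12, 9 when adjusted over the list alone (median -0.80, adjusted p = 0.823 with an estimated correlation). Matrix genes fell in 7 of 20, 10 when adjusted over the list alone (median -0.95, adjusted p = 0.951 with an estimated correlation), with Acta2 at -1.10 ± 0.26. In the list of proximal tubule S1 and S2 markers 5 of 14 fell and 1, the urate transporter gene Slc22a12 (0.50), rose. Adjusted over the list alone, 7 fell and 1 rose (median -0.74, adjusted p = 0.832 with an estimated correlation). Vitamin D, calcium and phosphate genes fell in 5 of 19 by both counts (median -0.56, adjusted p = 0.774 with an estimated correlation). Among them were the vitamin D receptor gene Vdr (-1.01 ± 0.25), Kl, the FGF23 co-receptor (-0.99 ± 0.33), and the calcium pump genes Atp2b1 (-0.42 ± 0.09) and Atp2b4 (-1.05 ± 0.36). Trpm7 (-0.66 ± 0.12, adjusted p = 7.39e-05) was the distal tubule marker that fell, 1 of 9 by both counts (median -0.66, adjusted p = 0.832 with an estimated correlation). In all, camera called 8 of 43 lists in Al, 0 with an estimated correlation (0 below an unadjusted p of 0.05), and fry called 11.

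Further genes that fell in Al were Lyve1 (-1.89 ± 0.56), Aplnr (-1.74 ± 0.48) and Calcrl (-1.68 ± 0.52), all expressed by endothelial cells, Sema3d (-1.64 ± 0.44), the complement gene C7 (-1.80 ± 0.63), Ugt2b7 (-1.68 ± 0.58), Trank1 (-1.85 ± 0.71) and Ypel4 (-1.77 ± 0.68). Rps28 rose from 45.7 ± 5.98 to 154 ± 32.1 CPM (1.75 ± 0.17, adjusted p = 6.19e-10), and Rpl38 (1.74 ± 0.19), Hspe1 (1.06 ± 0.15), Bax (0.76 ± 0.11), Ahsa1 (0.45 ± 0.08), ND3 (1.07 ± 0.20) and Sct, which encodes secretin (2.42 ± 0.75), rose. The rises of Rpl27-l1 (2.03), Rps15al4 (1.80), Rpl31l4 (1.63), Rpl37 (1.56), Hist2h2aa2 (1.92), Chchd2 (1.58) and Mt1m (1.57) concern genes with near-identical copies and are uncertain. Besides Cyp24a1, 5 of the 31 named genes that passed the test lost the call without 1 library. Their highest adjusted p-values were those of Ypel4 (adjusted p = 0.690) and C7 (0.160) without Ta replicate 4, Trank1 (0.143) without Ta replicate 3, and Slc4a4 (0.0770) and Ugt2b7 (0.0627) without Al replicate 5. In those fits the log2 fold changes were -0.39 for Ypel4, -1.18 for C7, -1.43 for Trank1, -1.52 for Slc4a4 and -1.55 for Ugt2b7. The libraries whose single absence ended the call numbered 10 for Ypel4, 6 for C7, 12 for Trank1, 9 for Slc4a4 and 4 for Ugt2b7. The count of 3996 became 272 with the small-protein covariate, 975 with surrogate variables, 1563 with cell make-up covariates and 2404 with a circadian covariate. The small-protein balance was 2.14 ± 0.41 in Al. Al libraries were uneven too: the mean log2 CPM of endothelial markers was 5.21 to 5.28 in Al replicates 1, 3 and 4, within the Ta range, and 3.35 to 4.22 in the other 5, below every Ta library.

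Lead pellets gave the most genes past the test. Kdr fell from 42.1 ± 4.26 CPM in Ta (n = 8) to 3.07 ± 1.40 CPM in Pb (n = 7; -3.77 ± 0.63, adjusted p = 2.07e-06), and Esm1, another endothelial gene, from 15.4 ± 2.46 to 1.11 ± 0.89 CPM (-3.76 ± 0.77, adjusted p = 6.02e-05). Podxl, the main sialoprotein of podocyte foot processes, fell by 3.19 on the log2 scale (SE 0.52, adjusted p = 1.45e-06), Synpo by 2.47 (SE 0.35, adjusted p = 9.73e-08) and Cd2ap by 1.10 (SE 0.10, adjusted p = 1.03e-11). Igfbp3 fell from 48.5 ± 21.0 to 4.97 ± 1.36 CPM (-3.29 ± 0.74, adjusted p = 0.000196), and C7 from 141.1 ± 139.9 to 11.6 ± 2.02 CPM (-3.61 ± 0.72, adjusted p = 4.25e-05). Each of these 7 genes lay below the Ta median in 7 of 7 libraries.

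All 11 podocyte markers fell in Pb, by both counts adjusted over all genes and adjusted over the list alone (median -1.88). Endothelial markers fell in 10 of 12, 10 lower and 1 higher when adjusted over the list alone (median -1.68), with Tek at -2.56 ± 0.45 and Pecam1 at -2.23 ± 0.38. Fibroblast and pericyte markers fell in 11 of 13, 12 when adjusted over the list alone (median -1.63), with Rgs5 at -3.06 ± 0.45 and Pdgfrb at -2.67 ± 0.52. Matrix genes fell in 14 of 20, 15 when adjusted over the list alone (median -1.64), with Acta2 at -1.65 ± 0.28 and Sparc at -1.71 ± 0.32. For these lists, and for every other list called in Pb, the adjusted p = 0.857 with an estimated correlation. Beside them, the small-protein balance was 2.90 ± 0.45 in Pb against 1.19 ± 0.24 in Ta. The mean log2 CPM of podocyte markers was 2.50 ± 0.36 against 4.51 ± 0.27, and that of endothelial markers 3.76 ± 0.33 against 5.38 ± 0.15, with all 7 Pb libraries below every Ta library in both.

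In the proximal tubule S1 and S2 list 10 of 14 fell and 1 rose, 12 and 1 when adjusted over the list alone (median -0.97). The bicarbonate transporter gene Slc4a4 (-2.98 ± 0.67), the neutral amino acid transporter gene Slc6a19 (-2.82 ± 0.65) and the organic anion transporter gene Slc22a8 (-2.42 ± 0.53) fell, and Slc22a12 (0.86 ± 0.19) rose. Vitamin D, calcium and phosphate genes fell in 13 of 19 and rose in 2 by both counts (list median -0.90). Kl stood at -2.18 ± 0.36, Vdr at -1.85 ± 0.27, Atp2b4 at -2.40 ± 0.40 and the sodium-calcium exchanger gene Slc8a1 at -2.18 ± 0.39. Distal tubule markers fell in 6 of 9 by both counts, with Slc12a3, the thiazide-sensitive transporter, at -1.99 ± 0.48 and Trpm7 at -1.17 ± 0.13 (list median -1.17). The adjusted p of these 3 lists was 0.857 with an estimated correlation.

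Of 21 oxidative phosphorylation genes 18 rose in Pb by both counts, Cox5b from 189.8 ± 28.98 to 545 ± 68.2 CPM (1.52 ± 0.12, adjusted p = 2.65e-14), with Cox6a1 (1.12 ± 0.09), Cox4i1 (0.96 ± 0.10) and Cox5a (0.77 ± 0.09) next. Of 13 mitochondrially encoded genes 10 rose, 11 when adjusted over the list alone, ND3 by 1.85 ± 0.20 (adjusted p = 0.857 with an estimated correlation for both lists). Mitochondrially encoded genes took 22.6 ± 1.30% of counts in Pb against 19.5 ± 2.52% in Ta. In the heme list, which holds enzymes that lead is known to inhibit, 9 of 13 rose and 2 fell by both counts (median 0.55, adjusted p = 0.857 with an estimated correlation). Urod rose by 0.75 ± 0.09 (adjusted p = 1.99e-09), Blvrb by 0.96 ± 0.12, Cpox by 0.83 ± 0.15 and Alad, the enzyme most sensitive to lead, by 0.55, and Fech, the ferrochelatase, fell by 0.25 on the log2 scale. The rise was not particular to lead: camera called this list higher in W and Co as well. Blvrb, Cpox and Urod also rose in Co, and Blvrb in DU (0.46).

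Among metal-handling genes, a list that camera did not call in Pb (adjusted p = 0.686), 5 of 16 rose and 8 fell by both counts. The ferritin genes Fth1 (0.94 ± 0.14) and Ftl1 (0.56 ± 0.10) and the metallothionein gene Mt3 (2.94 ± 0.76) rose, and the transferrin receptor gene Tfrc (-1.49 ± 0.26) and the zinc transporter gene Slc39a10 (-1.50 ± 0.23) fell. Other genes with large rises were Rpl38 (2.59 ± 0.20), Rps28 (2.49 ± 0.18), Rps21 (2.24 ± 0.17), Gng13 (2.35 ± 0.31), Hspe1 (1.55 ± 0.15), Bax (1.19 ± 0.12), Fam25a (2.26 ± 0.50), Glycam1 (3.03 ± 0.87) and Sct (2.78 ± 0.77), and, as uncertain copies, Hist2h2aa2 (2.98), Rps15al4 (2.35) and Rpl37 (2.26). Slc15a1 (-3.52 ± 0.88), Itga11 (-3.51 ± 0.84), Prima1 (-3.38 ± 0.88), Slc7a2 (-3.32 ± 0.84), Adcy1 (-3.22 ± 0.56) and Vegfd (-3.20 ± 0.72) fell. Of 43 lists camera called 10 in Pb, 0 with an estimated correlation (0 below an unadjusted p of 0.05), and fry called 22. The count of 8517 became 400 with the small-protein covariate and 1463 with surrogate variables. With the small-protein covariate the call of Kdr ended and that of Cox5b held, while Glycam1 (-0.50) and Prima1 (0.76) changed sign.

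In kidneys with depleted uranium, many of the largest rises lost their call without DU replicate 6. Lcn2, which encodes the injury marker NGAL, averaged 1081 ± 2891 CPM in DU against 30.2 ± 40.5 in Ta (mean ± SD, n = 8 each; 5.16 ± 1.10 SE, adjusted p = 0.000903), above the Ta median in 7 of 8 libraries. Much of this came from DU replicate 6, at 8234 CPM, where the highest other DU library had 155.0 and the highest Ta library 124.8 CPM. Without it Lcn2 stood at 1.00 ± 0.69 (adjusted p = 0.401). DU replicate 6 also stood apart in the mean log2 CPM of proximal tubule S1 and S2 markers. It had 5.83, against 7.66 to 8.99 in the other DU libraries and 8.34 to 8.71 in Ta. Mitochondrially encoded genes took 11.8% of its counts, the lowest share of all libraries. Of the other genes with the largest rises, Fgb (6.25 ± 1.10), Fgg (5.94 ± 1.04) and Glycam1 (4.80 ± 0.90) passed the test without DU replicate 6, at 1.78 ± 0.62 (adjusted p = 0.0493), 1.99 ± 0.63 (adjusted p = 0.0290) and 2.16 ± 0.69 (adjusted p = 0.0308). In the other 7 DU libraries Fgg had a median of 1.10 and a maximum of 19.9 CPM, against a Ta maximum of 2.25. Fgb had a median of 10.9 CPM there against a Ta maximum of 19.6. Without that library the calls ended for C3 (4.59, then 0.77 with adjusted p = 0.409), S100a8 (6.86, then 2.52 with adjusted p = 0.132), S100a9 (then 1.91 with adjusted p = 0.236), Cxcl1 (5.89, then 1.88 with adjusted p = 0.173), Cxcl2 (6.26, then 1.97 with adjusted p = 0.245), Cxcl6 (6.13, then 1.37 with adjusted p = 0.500), C4bpa (5.37, then 1.53 with adjusted p = 0.408), Fga (4.33, then 0.88 with adjusted p = 0.0673), Havcr1 (2.61, then 0.74 with adjusted p = 0.506), Timp1 (2.11, then 0.65 with adjusted p = 0.378) and Hmox1 (1.88, then 0.75 with adjusted p = 0.262).

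The falls named here kept their calls without that library. Cyp2c11, a male-specific cytochrome P450, fell from 40.5 ± 35.0 to 4.12 ± 2.94 CPM (-3.29 ± 0.61, adjusted p = 0.000162), below the Ta median in 8 of 8 libraries. It stood at -3.09 ± 0.62 (adjusted p = 0.000399) without DU replicate 6. Erc2, a protein of the presynaptic active zone, fell by 1.76 on the log2 scale (SE 0.32, adjusted p = 0.000148, 8 of 8 libraries). Anxa13 (-2.09 ± 0.50), Serpinb12 (-3.31 ± 0.93), Slitrk1 (-1.96 ± 0.40), Epha3 (-1.91 ± 0.44), Nkx1-2 (-1.92 ± 0.50), Frmd1 (-2.02 ± 0.52), Grpr (-1.83 ± 0.54) and Cpne4 (-1.72 ± 0.52) fell. Cpne4 lost its call without Ta replicate 1 (adjusted p = 0.0594). Cox5b (1.05 ± 0.11), Cox6a1 (0.75 ± 0.09), Bax (0.85 ± 0.11), Manf (0.85 ± 0.13) and Hspe1 (0.78 ± 0.15) rose, with adjusted p-values from 4.00e-09 to 0.000170.

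Camera called 14 of 43 lists in DU, 10 higher and 4 lower, all at an adjusted p = 0.686 with an estimated correlation. With that correlation camera called 0 lists (1 below an unadjusted p of 0.05), and fry called 5. The tubular injury list had 8 of 22 members higher and 1, Sox9 (-0.69 ± 0.14), lower, or 10 and 1 when adjusted over the list alone (median 0.96). Cytokine and chemokine genes rose in 9 of 20, 13 when adjusted over the list alone (median 0.96), but without DU replicate 6 in 0 of these 9. Ccl20 went from 3.92 to 0.87 (adjusted p = 0.564), Il6 from 4.70 to 2.00 (adjusted p = 0.266) and Nfkbia from 1.02 to 0.50 (adjusted p = 0.0888). Complement genes rose in 4 of 14, 6 when adjusted over the list alone, and macrophage markers in 5 of 15, 7 when adjusted over the list alone. Without DU replicate 6 each of those calls ended, though all of the genes stayed above 0. C3 and Cd14 kept a small part of their change, 0.77 and 0.57 (adjusted p = 0.409 and 0.204), and others more of it. C1qa went from 1.17 to 0.89 (adjusted p = 0.150), Cfb from 0.92 to 0.71 (adjusted p = 0.152), C1qc from 1.16 to 0.68 (adjusted p = 0.248) and Cd163 from 2.90 to 1.76 (adjusted p = 0.245). In the erythroid list 4 of 11 rose, 7 when adjusted over the list alone. The 4 were the globin genes Hba-a2, Hbb (1.29 ± 0.30), Hbb-bs and Hbb-b1, which have near-identical copies and are uncertain. Endoplasmic reticulum stress genes rose in 6 of 18, 9 when adjusted over the list alone (Ddit3 0.68 ± 0.13, Atf4 0.75 ± 0.16), and oxidative phosphorylation genes in 8 of 21, 9 when adjusted over the list alone. Without DU replicate 6 the calls held for 4 of the 4 globin genes, 5 of the 6 endoplasmic reticulum stress genes and 8 of the 8 oxidative phosphorylation genes. In the p53 list Bax, Btg2 (0.74 ± 0.20), Gadd45b (0.86 ± 0.27), Plk3 (0.83 ± 0.27) and Gadd45a (0.30 ± 0.10) rose and Sesn1 (-0.38 ± 0.13) fell, 8 and 2 of 19 when adjusted over the list alone. Of these 6, Bax and Btg2 kept their call without DU replicate 6. The matrix list, called higher, had 1 member past the test and 0 when adjusted over the list alone. Urothelium markers were called higher with 0 of 10 members past the test by both counts (median 1.02).

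Lower in DU were the renin-angiotensin list, with 3 of 11 by both counts, among them the peptidase genes Mme (-1.41 ± 0.29) and Enpep (-0.68 ± 0.15), and the gluconeogenesis and ammonia list with 1 of 12 by both counts (Glud1 -0.53 ± 0.13). So were the podocyte list with 1 of 11 by both counts (Cd2ap -0.33 ± 0.10) and the intercalated cell list with 0 of 11 by both counts (median -0.17). For each list the adjusted p = 0.686 with an estimated correlation. The glutathione synthesis genes Gclc (-1.48 ± 0.35) and Gclm (-0.91 ± 0.23) and Me1 (-0.61 ± 0.16) fell. They were the 3 members called lower in an NRF2 list with 1 member, Hmox1 (1.88), called higher. Camera did not call that list in DU (adjusted p = 0.893). Its median (0.15) and test (lower) differed in sign. Without DU replicate 6 the lists called fell from 14 to 6. The DU count of 2424 became 517 with the small-protein covariate and 4548 with limma voom. Its division into 1252 higher and 1172 lower genes was not stable. There were 1420 and 894 with RLE factors, 1113 and 579 without Ta replicate 2, 1145 and 633 without Ta replicate 1, and 1187 and 760 without DU replicate 6. All 8 DU libraries had more genes with a count (17405 ± 333.1) than any Ta library (15912 ± 616.9). So did 6 of 8 Al libraries (mean 16870) and 5 of 7 Pb libraries (mean 16715).

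**Figure D2:**
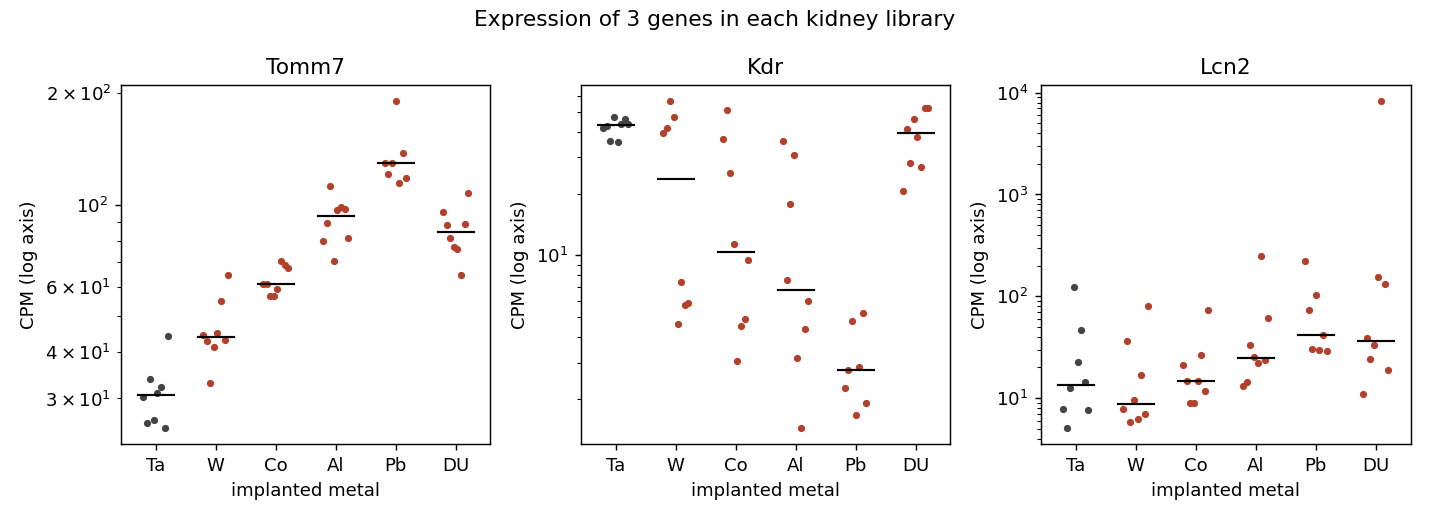
CPM of Tomm7, Kdr and Lcn2 in each of the 47 libraries on a log axis, by implanted metal on the x axis; points are single kidneys and lines are group medians. Kdr had a median of 43.0 CPM in Ta and 2.78 in Pb, Tomm7 of 30.7 and 129.4 CPM, and the highest Lcn2 value, 8234 CPM, was in DU.

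A panel of 12 genes of kidney injury, metal binding and oxidative stress was read in every comparison, whatever the test. None of the 12 passed the test in W or Co. In Pb, the metallothionein gene Mt2A rose from 463 ± 79.8 to 875 ± 352 CPM (0.92 ± 0.34, adjusted p = 0.0213, 6 of 7 libraries), but not without Pb replicate 4 (0.73, adjusted p = 0.0769). Cyp24a1 fell by 0.90 on the log2 scale (SE 0.28, adjusted p = 0.00704). In DU, Mt2A rose by 1.63 ± 0.34 (adjusted p = 0.000672, 7 of 8 libraries) and by 0.79 ± 0.22 without DU replicate 6 (adjusted p = 0.0126). The injury genes Havcr1 (1.13 ± 0.75, adjusted p = 0.209), Lcn2 (1.32 ± 0.97, adjusted p = 0.256), Spp1 (1.08 ± 0.61, adjusted p = 0.134), Clu (0.71 ± 0.51, adjusted p = 0.245) and Timp1 (0.62 ± 0.57, adjusted p = 0.373) did not pass the test in Pb, although Havcr1, Lcn2, Spp1 and Timp1 lay above the Ta median in 7 of 7 libraries and Clu in 6. Without Ta replicate 4 Spp1 was called (1.65, adjusted p = 0.0221). Clu in DU (1.19 ± 0.50, adjusted p = 0.0996) was called without Ta replicate 4 (1.64, adjusted p = 0.0185), and Umod in DU (-0.59 ± 0.27, adjusted p = 0.137) without DU replicate 1 (-0.79, adjusted p = 0.0394). Mt1 in DU (0.90 ± 0.33, adjusted p = 0.0536) was called without any 1 of Ta replicate 4 (adjusted p = 0.0426) and DU replicates 1 (0.0224), 2 (0.0435), 3 (0.0254), 4 (0.0342) and 7 (0.0396). Without DU replicate 6, Clu in DU stood at 0.31 (adjusted p = 0.723), Mt1 at 0.51 (adjusted p = 0.287) and Umod at -0.41 (adjusted p = 0.2997). That library had 5083 CPM of Clu, 1971 of Mt1 and 484 of Umod. Medians of the other DU libraries were 420.1, 433.7 and 2591 CPM in that order. Nqo1 and Cdkn1a passed in no comparison. Their log2 fold changes ran from -0.16 to 0.02 and from -0.52 to 0.39.

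Across all 6 metals 9260 genes differed, and 8436 differed among the 5 metals without reference to Ta. Tmem256 averaged 31.4 ± 5.60 CPM in Ta, 45.0 ± 4.66 in W, 63.1 ± 12.1 in Co, 81.3 ± 10.7 in Al, 124.1 ± 14.5 in Pb and 74.6 ± 10.8 in DU (SD; adjusted p = 4.08e-17 over 6 metals and 1.21e-11 over 5). Tomm7, a subunit of the mitochondrial import pore, went from 31.1 ± 6.20 in Ta to 134.3 ± 25.9 in Pb. Cox7c, Ndufa1, Cops9, Naa38, Rps28, Rps21, Sem1 and Tmem238 gave adjusted p-values from 4.19e-15 to 7.72e-14 over 6 metals. Arpp19, a phosphatase inhibitor, joined the first 10 among the 5 metals (32.3 ± 4.78 CPM in W and 68.4 ± 6.75 in Pb, adjusted p = 5.80e-10). The ribosomal protein genes, chosen after the data were seen, rose in 5 of 72 in W, 69 in Co, 68 in Al, 72 in Pb and 68 in DU, while the genes of very large proteins fell in 0 of 38, 18, 13, 29 and 6.

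Single pairs of metals were compared in the same fit. Pb differed from DU in 7867 genes, from W in 6186, from Co in 4100 and from Al in 3024. DU differed from Co in 3993, from W in 3284 and from Al in 2010, whereas Al differed from W in 426. EdgeR called 0 genes between W and Co, with 1460 below an unadjusted p of 0.05, and 0 between Co and Al, with 1196; other tools were not run for these pairs. Kdr was lower in Pb than in each of W (-3.08 ± 0.61, adjusted p = 7.82e-05), Co (-2.57 ± 0.60, adjusted p = 0.00137), Al (-2.12 ± 0.59, adjusted p = 0.00960) and DU, where the difference of DU from Pb was 3.63 ± 0.62 (adjusted p = 9.09e-06). Cox5b was higher in Pb than in W (1.15 ± 0.11), Co (0.80 ± 0.11) and Al (0.39 ± 0.11). Lcn2 was higher in DU than in W (5.67 ± 1.13), Co (5.59 ± 1.13), Al (4.29 ± 1.06) and Pb (3.84 ± 1.09, adjusted p = 0.00329). DU replicate 6, at 8234 CPM, enters each of these values, and they were not tested without it. The other 7 DU libraries ran from 10.9 to 155.0 CPM, the Pb libraries from 28.8 to 222.2 and the Al libraries from 13.2 to 249.5. Cyp2c11 was lower in DU than in W (-3.95 ± 0.63), Co (-3.55 ± 0.62), Al (-3.68 ± 0.62) and Pb (-2.42 ± 0.61, adjusted p = 0.000945). The podocyte list was lower in Pb than in Al (median -1.17, camera adjusted p = 0.000108, adjusted p = 0.888 with an estimated correlation). The fibroblast and pericyte list was higher in DU than in Al (median 1.28, camera adjusted p = 1.07e-06, adjusted p = 0.395 with an estimated correlation).

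Against Ta, 5394 genes were called in the same direction in at least 2 metals, 2658 higher and 2736 lower, while 66 genes were called in opposite directions by any metals. In 40 simulations every group, Ta included, was drawn from the same mean level per gene, independently for each gene. The mean and the highest such count were 0. With no gene changed almost none could be called, so this does not measure overlap that the shared Ta libraries cause. Higher in all 5 metals were 154 genes, led by Tomm7 (0.57 ± 0.12 in W, 1.01 ± 0.12 in Co, 1.55 ± 0.12 in Al, 2.11 ± 0.12 in Pb and 1.45 ± 0.12 in DU), Tmem256, Cox7c, Cops9, Rps28, Ndufa1, Sem1, Naa38, Cox14 and Rps21. There were 7 genes lower in all 5. Both counts need a call in W, whose own count went from 283 to 5 without W replicate 5. Without that library neither could exceed 5, so the counts for all 5 metals are not stable. Al and Pb shared 1995 higher and 1938 lower genes, and Pb and DU 1056 and 691, in comparisons that use the same Ta libraries. With separate Ta libraries for each metal, Al and Pb shared 1007 higher and 567 lower in 1 division of Ta and 1540 and 1273 in the other, and Pb and DU 691 and 278, then 546 and 231. Those fits use fewer libraries, which lowers the counts as well.

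Across genes, which are not independent replicates, log2 fold changes of Al and Pb correlated at 0.933 (simulated unchanged groups 0.480), those of Co and Al at 0.842 (0.501) and those of W and Co at 0.835 (0.500). Those of W and DU correlated at 0.04 (0.498) and those of Co and DU at 0.148 (0.500). The covariance was 0.338 for Al and Pb against a simulated 0.0307, and 0.00684 for W and DU against 0.0305, a difference of -0.0237. With the Ta libraries split between the metals, the correlation was 0.792 for Al and Pb and -0.0495 for W and DU. The count of 5394 became 232 with the small-protein covariate, 1228 with surrogate variables and 3330 with covariates of cell make-up.

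**Figure D3:**
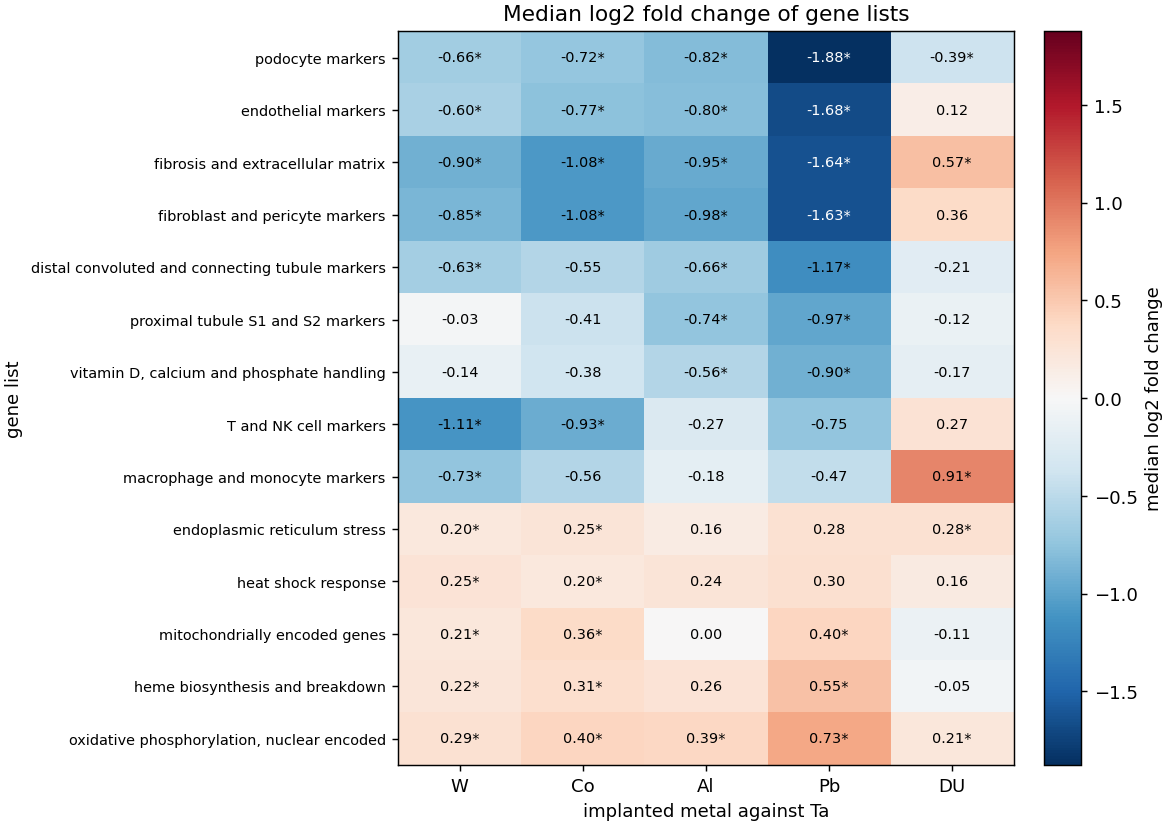
Median log2 fold change against Ta (colour and printed value) of the 14 fixed gene lists called by camera in at least 2 metals, with implanted metals on the x axis and lists on the y axis; an asterisk marks an adjusted p below 0.05 with the preset correlation. Podocyte markers had a median of -1.88 in Pb and -0.39 in DU, and none of these calls held with an estimated correlation.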

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

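The tests of explanations by gene size, cell make-up and a single DU library were chosen only after the results were seen, while the random splits were planned before.

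Ribosomal protein genes were called higher in 5, 69, 68, 72 and 68 of 72 in W, Co, Al, Pb and DU. In Pb the small subunits of the oxidative phosphorylation list exceeded the large ones by a median log2 fold change of 0.58. The exact permutation p was 0.0037 over 8 small and 9 large genes, with the other genes of the list left out. Those genes were measured in the same libraries and are not independent replicates, so this p does not measure the spread between animals. The lowest small subunit lay -0.0427 from the highest large one. With protein size standing in for transcript length, the difference in medians left a bias by size as a possible explanation. It argued against a rise alike of all subunits only for these genes, and the large ones rose too (median 0.42, 6 of 9 called). Animal numbers of the metal groups overlapped in 0 pairs, so a batch of handling or extraction could not be told apart from the metal. Genes that rose or fell with this balance may therefore reflect the libraries and not the kidneys.

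Podocyte and endothelial markers were lower in Pb, with a median of -1.88 (SE 0.2001) over 23 genes, of which 21 passed the test. A smaller share of cortex in the sampled tissue would have raised medullary genes. Thin limb and medullary markers had a median of -0.62 (SE 0.186 over 11 genes) and collecting duct markers of 0.01. A bias of the libraries by size could itself have lowered such genes, so these medians do not settle the share of cortex. With the small-protein balance as a covariate the median was -0.38 (SE 0.10004) and 1 of 23 genes passed. All 7 Pb libraries lay above every Ta library in this balance, so a loss of these cells and a bias of the libraries might each account for part, and the matter stays open.

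Injury and inflammation genes were higher in DU, and without DU replicate 6 cytokine calls went from 9 to 0, complement calls from 4 to 0 and macrophage calls from 5 to 0, yet some kept most of their change (C1qa from 1.17 to 0.89), which leaves the source of these open. For tubular injury 3 of 8 genes called higher kept their call, which argued against that library as the sole source there, although Lcn2 went from 5.16 (SE 1.10) to 1.00 (SE 0.692). The evidence is weak: Fgb passed at 0.0493, and Fgg had a median of 1.10 CPM in the other DU libraries, below the highest Ta value of 2.25. This test was redefined after its first form, on Lcn2 alone, had been seen. DU replicate 5 also lay above every Ta library in the mean log2 CPM of tubular injury genes (6.56 against at most 6.13). Its Havcr1 was 193 CPM, against at most 97.5 in Ta. Whether the 3 kept calls rest on DU replicate 5 was not tested. Lcn2 and C3 took 1.98% of the counts of DU replicate 6. That share leaves out other genes at high levels there, among them Spp1 (13296 CPM), Mt2A (5960), Clu (5083), Fga (4331) and Fgb (3888). It therefore does not settle whether a shift in composition moved other genes.

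Random splits of the same libraries into groups of the same sizes show whether chance can be excluded. For the shared direction such splits remove the differences of all groups at once. They do not measure overlap that the shared Ta libraries cause. Real counts were above the highest other split for W (283 against 2), Co (4089 against 936), Al (3996 against 1454), Pb (8517 against 7132), DU (2424 against 898), all 6 metals (9260 against 110.0), the 5 metals (8436 against 515) and the shared direction in at least 2 metals (5394 against 12). For gene lists chance could not be excluded: W had 14 with a highest other of 21, Co 12 with 21, Al 8 with 25, Pb 10 with 20 and DU 14 with 28. Of 100 splits, the real one included, 19, 32, 69, 53 and 59 gave as many lists, and 1 gave as many genes in each test of genes.

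A library was marked when the gap to its nearest neighbour took a large part of its group's range, which chance does in about 1 in 20 groups; 35 of 340 groups of values were marked. DU replicate 6 was marked 10 times, as the highest for Cxcl1 (0.562 of the range), Cxcl2 (0.618), Cxcl6 (0.55), Fga (0.659), Fgb (0.592), Hmox1 (0.542), Lcn2 (0.6), Manf (0.666) and Mt2A (0.553), and as the lowest for Hspe1 (0.57). W replicate 5 was the highest for Hspe1 (0.584) and the lowest for Inpp5d (0.548) and Mt1 (0.607). In Ta, replicate 4 stood apart for Cxcl2 (0.628), Erc2 (0.626), Umod (0.556) and Ypel4 (0.725), replicate 7 for Fam25a (0.672), Hist2h2aa3 (0.65) and the mitochondrial share (0.547, at 25.1%), replicate 6 for Mt1m (0.587) and Syce1l (0.654), replicate 3 for Sema3d (0.585) and Speg (0.548), replicate 8 for Rpl31l4 (0.565) and replicate 1 for its total (0.528, at 35775818 counts). In Al, replicate 6 stood apart for Bax (0.576) and Timp1 (0.582) and replicate 5 for Hist2h2aa2 (0.534). In Co, replicate 6 did for Kiss1 (0.717) and Fam25a (0.59) and replicate 5 for Zfp280b (0.591). In Pb, replicate 4 was the lowest for Trpm7 (0.757) and Cd2ap (0.599), and replicate 1 stood apart for C7 (0.616).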

How the results depend on the processing

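The small-protein covariate and the fits without 2 libraries were chosen only after the results were seen, and the cause of each change below was not tested unless stated. Of 204 named values, 191 kept direction and call with DESeq2 (of 203), 200 with RLE factors, 186 without a filter, 191 with replicate numbers as a block, 168 with only the groups compared (of 198) and 55 with the small-protein covariate. With the proximal tubule and collecting duct covariates of cell make-up 60 lost the call and 14 changed sign. Counts without 1 library ranged from 5 to 604 in W, 3036 to 4812 in Co, 3071 to 4435 in Al, 8081 to 8502 in Pb and 1692 to 2830 in DU. Genes near 1 CPM are those that depth limits.

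The W count was the least stable. It was 764 with DESeq2, 166 with upper quartile factors, 117 without a filter, 562 with a strict filter, 34 with cell make-up covariates, 90 with a circadian covariate, 67 at a fold of at least 1.5 and 996 at a threshold of 0.1. It was 0 with surrogate variables in edgeR (1332 below an unadjusted p of 0.05; DESeq2 without them called 764), 0 with the small-protein covariate (2327 below an unadjusted p of 0.05) and 1 without Ta replicates 4 and 6. Co had 2490 genes with cell make-up covariates, 179 with surrogate variables, 1503 at a fold of at least 1.5 and 15 with the small-protein covariate. Al had 1563, 975, 1487 and 272 in that order, and 2404 with the circadian covariate. Pb had 1463 with surrogate variables and 400 with the small-protein covariate. DU had 4548 with limma voom, 930 at a fold of at least 1.5 and 517 with the small-protein covariate. The fold minimum and the threshold change counts by construction.

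Genes differing among all 6 metals were 2475 with surrogate variables and 4241 with the small-protein covariate, and among the 5 metals 1860 and 4445. The count shared in direction was 3330 with cell make-up covariates, 1228 with surrogate variables, 2163 at a fold of at least 1.5 and 232 with the small-protein covariate. Lists called were 0 in each metal with an estimated correlation. With surrogate variables they were 8 in W, 5 in Pb and 5 in DU, with fry 2 in W, 22 in Pb and 5 in DU, and with cell make-up covariates 2 in Al. In DU they were 6 with the small-protein covariate, 23 without Ta replicates 4 and 6, and 5 without DU replicates 5 and 6. With replicate numbers as a block the counts were 317 in W, 4288 in Co, 4138 in Al, 8507 in Pb and 2387 in DU.

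Some log2 fold changes that had not passed the test changed sign without 1 library. Havcr1, Lcn2, Spp1 and Clu did so in W and in Co without Ta replicate 4. Lcn2, Spp1, Clu and Timp1 did so in Al without Al replicate 6, and Nqo1 in DU without DU replicate 6 (-0.34). These are examples. In the other settings log2 fold changes changed sign as follows. With DESeq2 they were Lcn2 in Al (-0.136), Mt1 in Pb (0.0107) and Umod in Pb (0.0003), with RLE factors Mt1 in Pb (0.0106) and Umod in Pb (0.0003), with only the groups compared Mt1 in Pb (0.0105), and with replicate numbers as a block Hmox1 in Co (0.0336) and Nqo1 in DU (-0.0702). With cell make-up covariates Mt1 was 0.076 in W, 0.209 in Co, 0.226 in Al and 0.598 in Pb. Hmox1 was 0.2997 in Co, 0.51 in Al and 0.248 in Pb, and Nqo1 was -0.0029 in W, -0.228 in Pb and -0.251 in DU. Umod was -0.154 in W and -0.0394 in Al, Cdkn1a 0.114 in Al and Cyp24a1 0.16 in Co.

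With the small-protein covariate Mt2A was -0.32 in W, -0.53 in Co, -0.69 in Al and -0.96 in Pb, and Nqo1 was -0.083 in W, -0.39 in Pb and -0.20 in DU. Umod was 0.29 in Co and 0.91 in Pb, and Cyp24a1 0.20 in Co and 0.034 in DU. Havcr1 was -1.57 in Al and -2.75 in Pb, Lcn2 -2.59 and -4.82, Spp1 -1.43 and -2.23, Clu -1.26 and -2.21, and Timp1 -1.49 and -2.54. Spp1 was -0.69 and Clu -0.37 in DU, and in Pb Glycam1 was -0.50 and Prima1 0.76. Of these, Mt2A, Glycam1 and Prima1 in Pb had passed the test without the covariate, and Lcn2 in Pb passed as lower with it (adjusted p = 0.0398). For each of these the cause was not tested. The balance did not overlap between Ta (0.78 to 1.52) and Pb (2.51 to 3.78), and every Co, Al and DU library also lay above every Ta library. Fits with this covariate therefore cannot separate the balance from the metal. The signs and the lower counts they gave rest on a slope carried across that gap. They do not show that Lcn2 fell in Pb.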

Other observations

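No test of this part was chosen to explain a result, and the gene groups were read after the main results had been seen. In Pb kidneys genes of the sterol synthesis pathway divided: of 20 genes 10 fell, among them Sc5d (-0.91 ± 0.12) and Srebf2 (-0.60 ± 0.10), and 3 rose, Fdps (0.34 ± 0.10), Mvk (0.33 ± 0.11) and Mvd (0.35 ± 0.12). Adjusted over the list alone 11 fell and 3 rose, and camera did not call the list (adjusted p = 0.109, and 0.857 with an estimated correlation). Fatty acid oxidation genes divided as well, with 9 of 20 lower and 4 higher by both counts, the carnitine transferase gene Cpt1a at -1.40 ± 0.19 and its regulator gene Ppara at -1.55 ± 0.35 (camera adjusted p = 0.690). Over all 15868 tested genes 4626 fell and 3891 rose in Pb, so a division in both directions is not particular to these lists.

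Circadian genes fell in 7 of 18 in Al and in 7 of 18 in Pb, Clock by -1.13 ± 0.26 and -2.26 ± 0.29, while camera did not call the list (adjusted p = 0.107 in Al and 0.266 in Pb). The angiotensin receptor gene Agtr1a was lower in Al (-1.20 ± 0.35) and Pb (-2.20 ± 0.38), and the angiotensinogen gene Agt higher in both (0.68 ± 0.23 and 1.13 ± 0.24). Tff3 and Krt19 rose in Pb (1.77 ± 0.29 and 1.16 ± 0.20) and in Al (1.10 ± 0.28 and 0.53 ± 0.20), although camera did not call the tubular injury list in either metal (adjusted p = 0.109 and 0.236).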
